A study of Mus musculus with 12 samples.

How the data were processed

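Argonaute (Ago) HITS-CLIP, in which RNA crosslinked to Ago protein is immunoprecipitated and sequenced, was performed on mouse fetal liver cells of strain C57BL/6J. The animals were wild type (WT) or lacked the miR-144/451 locus (KO). The 12 libraries fell into 4 groups of 3, precipitated from WT or KO liver with an Ago antibody or with control IgG. The labels speak of 3 replicates per genotype. Whether each library came from a separate liver, and whether an Ago and an IgG library shared one, is not given in the sources used here. The p-values of the tests per peak therefore measure the spread between these libraries, part of which may be technical. Libraries are named by their group and the library number in their title. Per the submitters' processing notes, cutadapt, STAR, bedtools and limma were used with genome build mm10. Their versions and roles are not given in the sources used here.

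The authors' deposited peak table held 106382 peaks called on the pooled Ago libraries, with a median width of 33 nt. Per the deposited column description, the counts are raw reads that overlap a peak by a minimum number of bases. The deposited coverage columns give the maximum read coverage of a peak per library, a signal not scaled for depth. The authors' IgG ratio is the summed IgG peak height over the summed Ago peak height, taken as the larger of the genotypes. The authors' density over background is a score with some values below 0 and served only to test which peaks their filter kept. The deposited seed codes are a score for the best seed match of each of 6 microRNAs near a peak, from a single mismatch or an offset 6-mer up to a 6-mer (code 11), 7-mer-A1 (12), 7-mer-m8 (13) and 8-mer (14). Other deposited columns by the authors gave the average coverage of the gene and the larger of the lowest WT and lowest KO peak heights. The authors' deposited table of differential peaks gave log2 fold changes of KO over WT from voom and limma, on a smaller set of peaks. Its p-values and false discovery rates are the authors' own and were described, not recomputed. Coordinates are mm10 as the deposited files give them. Of 12102 gene names, 11136 matched a RefSeq symbol and 513 only a synonym, and 453 did not match. Among the names, 15 had been turned into dates, which affected 332 peaks, and no such name is printed. The 22189 peaks without a gene were kept as intergenic peaks.

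Read counts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) after TMM scaling and filterByExpr with a minimum count of 10 and a minimum total of 15. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Each pairwise comparison used only the 6 libraries it is about, and the interaction of genotype and antibody used all 12. Levels are CPM values on the TMM-scaled reads of the tested peaks, given as mean and SD over libraries. Ratios of summed reads carry exact 95% intervals, and a group with 0 reads was set to 3 reads over the group to give a bound. Intervals and bounds cover counting error only, since no molecular identifiers are known to have been used. The log2 changes are those of the fit, and their standard errors were derived from its F statistic. The test was checked on simulated counts. For KO against WT in Ago libraries it recovered 27% of peaks changed 2-fold and 80% of those changed 4-fold, with 4 false calls. For Ago against IgG it recovered 82.0% of 4-fold changes in WT and 68.8% in KO. For KO against WT in IgG libraries it recovered 94.7% of 4-fold changes, and for the interaction 17%.

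Seed match groups held peaks with a deposited code of 7-mer-A1 or longer. Their share of lower peaks was compared by a two-sided Fisher exact test. Fisher exact tests, here and below, treat peaks as independent units, although peaks share genes and libraries. Their p-values therefore do not measure the spread between libraries. The shift of a seed match group was tested by camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated one. Gene lists fixed before the data were examined were literature targets of miR-144 or miR-451, erythroid, hepatocyte, macrophage, megakaryocyte, progenitor, granulocyte, Ago pathway, cytochrome c oxidase assembly, 14-3-3, FoxO3 with target genes, and abundant noncoding RNA with the Mir, Snord, Snora and mt- classes. The named genes follow a rule set before the data were examined. They are the 10 genes with the smallest p in each direction, at 1 peak per gene, and the 10 with the smallest p higher in Ago than IgG in WT. Literature targets with a tested peak, peaks over the deleted locus, and up to 4 called genes of each other list were added. Where no peak passed, the 5 with the smallest p were given. The list of higher genes is given without 1 of its 10 genes, which is not reported here. Peaks with the same counts in all 12 libraries, or counts within 10%, were marked as sharing reads with a near-identical copy.

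The alternatives set beforehand were library size or RLE scaling, no filter, a filter of 10 reads in 3 libraries, DESeq2 1.42.0, limma-voom, each library left out in turn, a 4-group fit, removal of peaks over microRNA genes, peaks enriched over IgG alone, other seed lengths, and a stricter threshold and looser overlap for the authors' table. Some alternatives were added after the data were seen and are named as such in the closing section. The numbers of the WT and KO libraries do not match. Their deviations from the group means nevertheless correlated when libraries were paired in number order, at 0.47, 0.59 and 0.43 for Ago (mean 0.50, the highest of 6 pairings) and 0.31, 0.22 and 0.21 for IgG (mean 0.24, the highest of 6 pairings). This pairing came from the data, not from the labels, so it served only as an added alternative. The seed search for other microRNA families, or over longer intervals, needs genome sequence and was not run. The chi-square over its degrees of freedom lay between 1.10 and 3.33 in the 12 pairs of libraries within groups. Across genotypes it was 0.873 for WT IgG library 11 with KO IgG library 14, which is no more than counting error gives. All libraries were kept as separate samples, as the labels have them.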

Results

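Ago-bound RNA was measured in fetal liver of WT mice and of mice lacking the miR-144/451 locus, whose microRNAs are abundant in erythroid cells. Each of the 4 groups (WT Ago, KO Ago, WT IgG, KO IgG) held 3 libraries. The WT Ago libraries 1, 9 and 10 held 292010, 452157 and 202876 reads in peaks. The KO Ago libraries 3, 12 and 13 held 198800, 341061 and 147969 reads. The WT IgG libraries 2, 6 and 11 held 37984, 42399 and 25985 reads, and the KO IgG libraries 4, 8 and 14 held 42916, 28882 and 24622 reads. Hepatocyte genes took 1.38% ± 0.875 of the peak reads in WT Ago and 2.03% ± 0.786 in KO Ago (SD, n = 3 each). In IgG libraries they took 2.56% ± 0.522 in WT and 2.83% ± 0.530 in KO (SD, n = 3 each). Erythroid genes took 2.57% ± 0.236 in WT Ago and 2.02% ± 0.171 in KO Ago, and 2.10% ± 0.598 in WT IgG and 2.32% ± 0.589 in KO IgG (SD, n = 3 each).

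**Figure D1:**
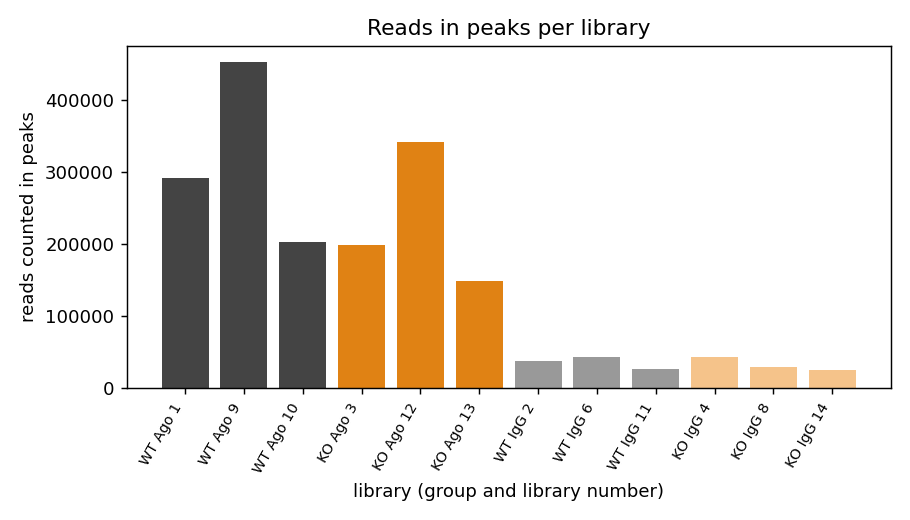
Reads counted in peaks (vertical axis) for each of the 12 libraries (horizontal axis), with 1 bar per library and colours by group. The Ago libraries held 147969 to 452157 reads and the IgG libraries 24622 to 42916.

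The targeted locus was examined first. Mir144 lies at chromosome 11, 78073005 to 78073070, and Mir451a at 78073170 to 78073241 (mm10). No peak analysed here overlapped Mir144, Mir451a or Mir451b. The nearest peak, at 78072782 to 78072812, ended 193 nt upstream of Mir144 and held 7 WT and 3 KO Ago reads. The deletion could therefore not be checked at the locus itself, and the genotype is taken from the labels.

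The comparison of KO with WT in Ago libraries asked which Ago-bound sites depend on the deleted microRNAs. Ago reads fell far more often than they rose. The 3′UTR peak of Tnrc6b, a scaffold protein of the Ago silencing complex, fell from 850 ± 140 CPM in WT to 38.8 ± 20.2 in KO (SD, n = 3 each). A 3′UTR peak of Nek2, a mitotic kinase, fell from 838 ± 214 to 19 ± 19, and a coding peak of Larp1, an RNA-binding protein, from 1114 ± 197 to 93 ± 19.1. The 3′UTR peak of Ybx1, an RNA- and DNA-binding protein, fell from 621 ± 122 to 6.32 ± 10.9. Among the peaks that rose, the 3′UTR peak of Sbno1 went from 59.1 ± 32.7 to 317 ± 121, and a coding peak of Gadd45a, a stress-response gene, from 178 ± 72.9 to 488 ± 38.6.

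Of 2425 tested peaks, 428 were lower and 34 higher in KO by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and 641 had an unadjusted p under 0.05. The tested peaks of a library held 25097 to 63658 reads. The median log2 change of all tested peaks was 0.09 with TMM scaling and 0.25 with library size alone, so changes are relative to that level. The lower peaks lay in 308 of 1164 tested genes, of which 58 held at least 2 lower peaks, and 26 lower peaks were intergenic. The higher peaks lay in 28 genes, and 4 genes held both kinds.

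The 10 genes named as lowest by p had edgeR quasi-likelihood adjusted p = 7.1e-05 each, with lower levels in all 3 KO libraries than in any WT library. The log2 changes were -3.91 ± 0.42 for an intron peak of Tnfaip2 (fitted change ± SE, n = 3 each), -4.47 ± 0.48 for Tnrc6b, -5.36 ± 0.58 for Nek2 and -3.50 ± 0.38 for Larp1. They were -3.48 ± 0.39 for the 3′UTR of Ube2l6, -5.71 ± 0.65 for Ybx1, -5.78 ± 0.67 for an intron of Wdhd1 and -5.63 ± 0.66 for the coding sequence of Ncoa7. WT reads exceeded KO reads 24.6-fold for Tnrc6b (95% counting interval 9.35 to 91.7) and 11.8-fold for Larp1 (6.39 to 24.1). The peaks of Ybx1, Wdhd1 and Ncoa7 each held 1 KO read, with ratios of 69.7 (12.2 to 2787), 71.4 (12.5 to 2853) and 67.2 (11.7 to 2687). Fau, a ribosomal protein gene, had a log2 change of -4.30 ± 0.48 and Gm9843 one of -3.84 ± 0.45. Their counts nearly coincided across libraries, so both are uncertain, since reads of one can map to the other.

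The genes named as highest had smaller changes. The log2 changes were 2.29 ± 0.50 for Sbno1 (fitted change ± SE, n = 3 each; edgeR quasi-likelihood adjusted p = 0.0028), 1.97 ± 0.48 for Cmas (adjusted p = 0.0067), 1.51 ± 0.39 for Rc3h2 (adjusted p = 0.0093) and 1.33 ± 0.35 for Ell2 (adjusted p = 0.011). An intron peak of Cpeb4 rose by 1.15 ± 0.30, and the named peaks of other genes rose, Msl2 by 1.15 ± 0.31, Tmcc2 by 1.35 ± 0.36, Gadd45a by 1.41 ± 0.39 and Tnrc6a by 1.33 ± 0.37, with edgeR quasi-likelihood adjusted p from 0.012 to 0.016. Cpeb4 also held 3 lower peaks among 12 tested, and Ell2 held 1. Over the alternatives, 46 of 176 values for the higher named peaks lost the call, in all but Sbno1, against 0 of 191 for the lower named peaks. Those of Gadd45a and Tnrc6a were lost by DESeq2, with no filter and without WT Ago library 1, among others. The count of higher peaks rested on single libraries and on the tool: 3 without WT Ago library 1, 14 without KO Ago library 12, 54 without KO Ago library 3, 7 by DESeq2 and 69 with library size alone. With number-ordered library pairs as a block, a choice made after the data were seen, it was 201, beside 533 lower peaks that included all 428. The count of lower peaks was 304 without WT Ago library 1 and 332 without WT Ago library 9. It was 802 without WT Ago library 10, 986 without KO Ago library 3 and 904 without KO Ago library 13, where more peaks passed the filter.

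**Figure D2:**
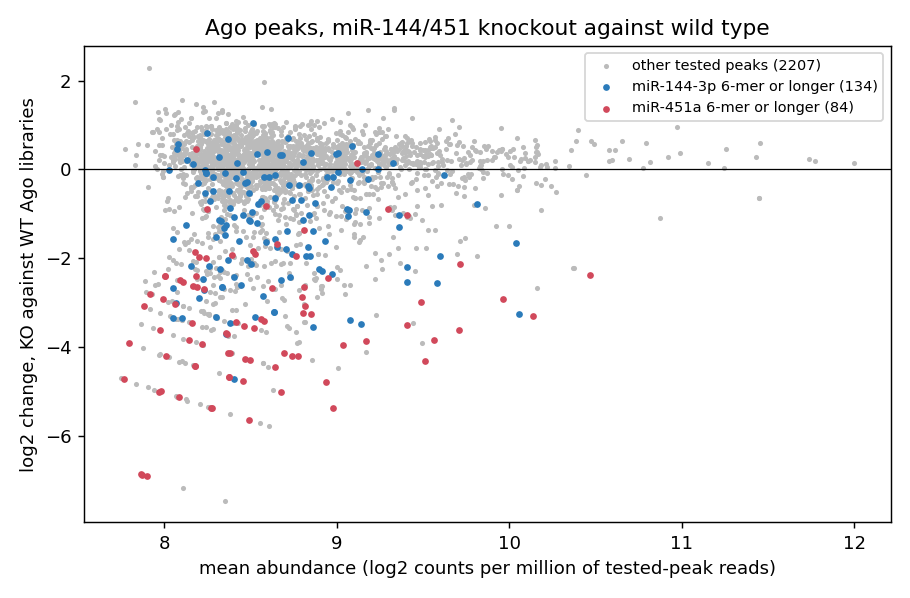
Log2 change of KO against WT in Ago libraries (vertical axis) against mean abundance in log2 CPM of tested-peak reads (horizontal axis), 1 point per tested peak. Red points are the 84 peaks with a miR-451a 6-mer or longer, of which 79 were called lower, blue points the 134 with a miR-144-3p 6-mer or longer, of which 61 were called lower, and grey points the other peaks.

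**Figure D3:**
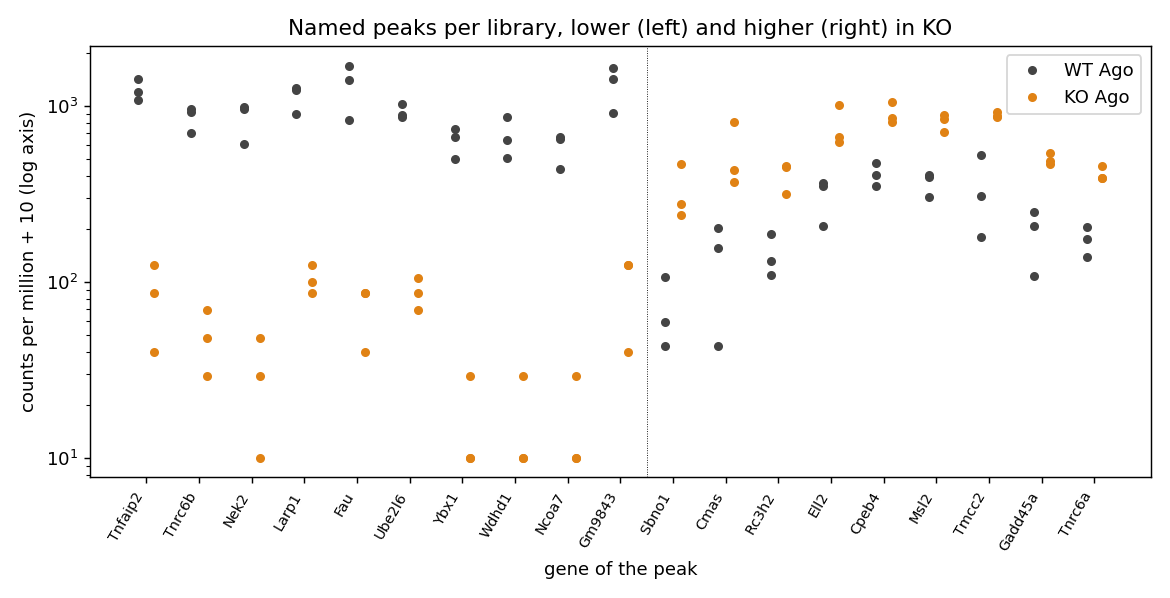
CPM plus 10 on a log axis (vertical axis) of each Ago library for the named genes (horizontal axis), WT in dark grey and KO in orange, 3 points per group. The genes left of the dotted line were lower in KO and those right of it higher, and the gap between groups is wider on the left.

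Tested peaks with a seed match to miR-451a, a Dicer-independent microRNA of the deleted locus, fell almost without exception. The filter kept 40 of 544 peaks with a 7-mer or longer miR-451a match, and 75 of 1768 with a miR-144-3p one. The others held too few reads to be tested. Of the 40 tested miR-451a peaks, 38 were lower and 2 did not pass, and their median log2 change lay at -3.10 relative to that of other peaks. Setting the 2 peaks with 0 KO reads to their bounds left that median as it was. For miR-144-3p, from the same locus, 41 of 75 peaks were lower and 34 did not pass, with a median of -1.30 against 0.11. For miR-144-5p, its passenger strand, 2 of 16 were lower, with a median of -0.07.

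The share of lower peaks was 95% among miR-451a peaks and 16.4% among others (odds ratio 97.0, 95% interval 24.9 to 820, Fisher exact p = 3.2e-27). For miR-144-3p the shares were 54.7% and 16.5% (odds ratio 6.11, 3.73 to 10.1, Fisher exact p = 1.8e-13). By camera with Benjamini-Hochberg adjustment over 6 families, the adjusted p was 1.6e-24 for miR-451a, and adjusted p = 0.034 with an estimated correlation. That estimated-correlation call was lost in 5 of 6 leave-one-out fits, with adjusted p = 0.064 without WT Ago library 1, 0.11 without WT Ago library 9, 0.15 without KO Ago library 3, 0.11 without KO Ago library 12 and 0.051 without KO Ago library 13, and held at 0.028 without WT Ago library 10. The median shift lay between -3.94 and -2.88 in these fits. For miR-144-3p the camera adjusted p was 1.1e-12, and the call was lost with adjusted p = 0.069 with an estimated correlation (unadjusted p = 0.023). For miR-144-5p the camera adjusted p was 0.99.

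Among microRNAs outside the locus, miR-16-5p peaks were called lower in 9 of 208 cases and higher in 1, with a median log2 change of 0.15 against 0.08 in other peaks. The odds ratio for being lower was 0.194 (0.0868 to 0.380, Fisher exact p = 3.2e-09), and camera gave adjusted p = 0.0074, which became adjusted p = 0.27 with an estimated correlation. Of the 428 lower peaks, 419 were among these other peaks, so the reference itself holds the peaks that fell. Of 1210 peaks without any code of the locus, 6.28% were lower, with a median of 0.21, against 4.33% of miR-16-5p peaks. The references for miR-122-5p and miR-21a-5p below are mixed in the same way. Of 47 peaks for miR-122-5p, the main microRNA of hepatocytes, 0 were lower and 1 was higher by the edgeR quasi-likelihood test, with 1 lower and 5 higher at an unadjusted p under 0.05. DESeq2 called 0 of them and limma-voom 1 higher. Their median log2 change was 0.39, with camera adjusted p = 0.0022 and adjusted p = 0.47 with an estimated correlation. The miR-122-5p shift against other peaks was 0.31, and 0.18 without WT Ago library 1, where the camera call was also lost. Of 9 miR-21a-5p peaks, 0 were called in either direction by the edgeR quasi-likelihood test, DESeq2 or limma-voom, with 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.092).

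**Figure D4:**
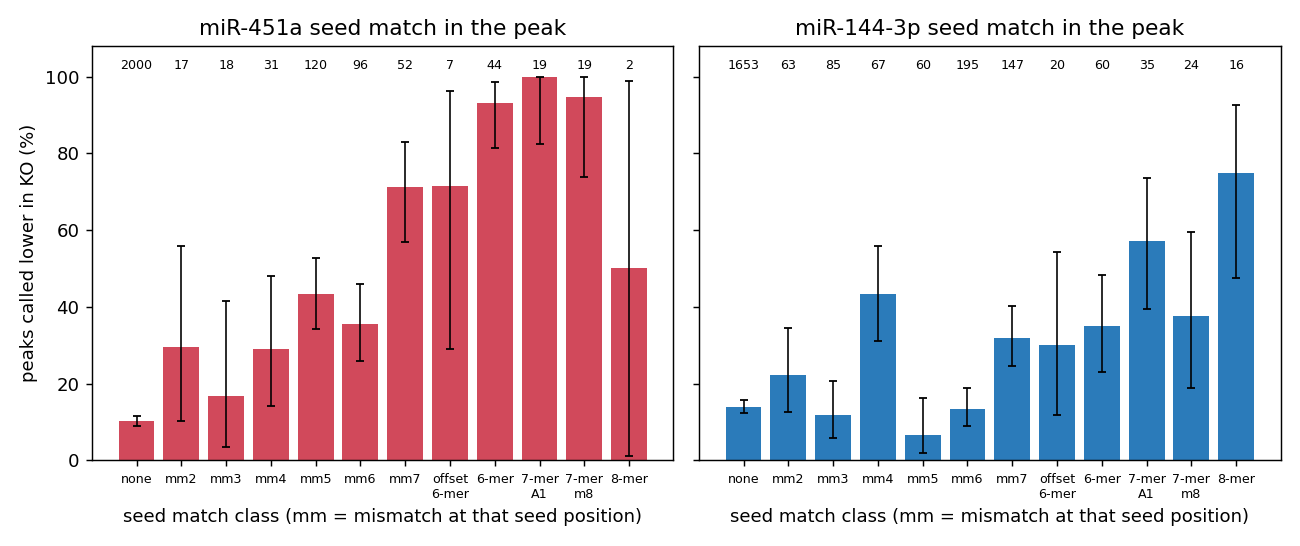
Percent of tested peaks called lower in KO (vertical axis) by seed match class (horizontal axis) for miR-451a and miR-144-3p, with exact 95% intervals as error bars and the number of peaks above each bar. For miR-451a, 94.7% of 7-mer-m8 and 93.2% of 6-mer peaks were lower, against 10.2% of peaks with no code.

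Of the 18 literature targets of miR-144 or miR-451, 4 had tested peaks. Of their 9 peaks, 5 were lower, 0 higher and 4 not called, and 5 were lower when adjusted over the list alone. A pair of peaks of Ezh2, the Polycomb methyltransferase, fell in coding sequence, by 2.88 ± 0.43 on the log2 scale with a miR-451a mismatch code and by 2.04 ± 0.40 with a miR-144-3p 7-mer (fitted change ± SE, n = 3 each; edgeR quasi-likelihood adjusted p = 1.8e-04 and 0.0013). The 3′UTR peak of Ywhaz, which encodes 14-3-3 zeta, fell from 416 ± 47.0 to 66.9 ± 43.1 CPM (SD, n = 3 each; edgeR quasi-likelihood adjusted p = 4.9e-04). The 3′UTR peak of Cab39, a partner of the kinase LKB1, fell from 477 ± 103 to 132 ± 17.2 (SD, n = 3 each; edgeR quasi-likelihood adjusted p = 0.0024). Both of those peaks held a miR-451a 7-mer-m8. An intron peak of Adam10, a membrane metalloprotease, had a log2 change of -1.44 ± 0.39 (edgeR quasi-likelihood adjusted p = 0.013), and the call was lost with DESeq2, with no filter and without KO Ago library 12. This peak held no code of miR-451a, miR-144-3p or miR-144-5p, while the 3′UTR peak of Adam10 with a miR-144-3p mismatch code had a log2 change of 0.23. The other Adam10 peaks had log2 changes of 0.64, 0.23 and -0.11, and the coding peak of Ywhaz, which shares its counts with Gm4202, had -0.29, and none of these passed. For the whole list the camera adjusted p was 0.076, and adjusted p = 0.69 with an estimated correlation.

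Erythroid genes held the most lower peaks of the fixed lists by number, and also the most tested peaks. Of 154 tested peaks in 23 genes, 41 in 18 genes were lower, 1 was higher and 112 did not pass, and 47 were lower and 1 higher when adjusted over the list alone. Over all tested peaks, 428 of 2425 were lower. Of the 41 lower erythroid peaks, 33 held a code of the locus, and of all 428 lower peaks 76 held none. A 3′UTR peak of Tfrc, the transferrin receptor, fell from 1802 ± 360 to 188 ± 90.4 CPM (SD, n = 3 each) and held a miR-144-3p 7-mer-m8. The 3′UTR peak of Slc25a37, the mitochondrial iron importer, fell from 1861 ± 48.0 to 296 ± 64.9, a coding peak of Epor, the erythropoietin receptor, from 861 ± 137 to 52.2 ± 60.7, and a coding peak of Alas2, the first enzyme of erythroid haem synthesis, from 524 ± 179 to 38.8 ± 20.2. Their log2 changes were -3.25 ± 0.39, -2.67 ± 0.33, -3.95 ± 0.52 and -3.76 ± 0.54 (fitted change ± SE, n = 3 each; edgeR quasi-likelihood adjusted p = 7.1e-05 to 1.5e-04). Several genes held many lower peaks, with 7 of 26 in Slc25a37, 7 of 24 in Slc4a1 (the band 3 anion exchanger) and 6 of 10 in Tfrc. Few of these lower peaks held a full seed match. A miR-451a 6-mer or longer was held by 1 in Slc25a37, 0 in Slc4a1 and 0 in Tfrc. A miR-144-3p 6-mer or longer was held by 0, 0 and 1 in the same order. The list's median log2 change was -0.46, with camera adjusted p = 0.0028, and the call was lost with adjusted p = 0.69 with an estimated correlation. With the library pairs as a block, the unadjusted camera p was 0.028 with an estimated correlation.

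Hepatocyte genes lay slightly above 0 as a set. Of 112 tested peaks in 14 genes, among them Alb (albumin), Afp (alpha-fetoprotein) and Trf (transferrin), 110 had a positive log2 change, and the median was 0.40. None was called by the edgeR quasi-likelihood test (0 lower, 0 higher, with 0 and 7 at an unadjusted p under 0.05), adjusted over the list alone, by DESeq2 or by limma-voom. The camera adjusted p was 1.1e-06, and the call was lost with adjusted p = 0.69 with an estimated correlation, which was 0.787. The share of reads in hepatocyte genes was 0.805%, 0.945% and 2.38% in WT Ago libraries 1, 9 and 10 and 1.51%, 1.64% and 2.93% in KO Ago libraries 3, 12 and 13. Without WT Ago library 1 the median was 0.0029, without WT Ago library 9 0.17, without KO Ago library 13 0.18 and without WT Ago library 10 0.86. In alternatives chosen after the data were seen, it was 0.43 with the library pairs as a block and 0.70 without WT 10 and KO 13 together. The unadjusted camera p with an estimated correlation was then 0.31 and 0.071.

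Genes of the Ago pathway went both ways. Of 18 tested peaks, 2 were lower and 2 higher, also when adjusted over the list alone. The lower peaks were those of Tnrc6b and Dicer1, the microRNA-processing nuclease, whose coding peak with a miR-144-3p 7-mer-A1 had a log2 change of -2.03 ± 0.41 (fitted change ± SE, n = 3 each; edgeR quasi-likelihood adjusted p = 0.0018). Both higher peaks lay in Tnrc6a, a paralog of Tnrc6b, and DESeq2 called neither. The camera adjusted p was 0.23, and adjusted p = 0.69 with an estimated correlation.

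Among the 14-3-3 genes only Ywhaz had tested peaks, 2 in number with 1 lower, also when adjusted over the list alone (camera adjusted p = 0.30). Of 22 peaks of FoxO3 and its target genes, 1 was lower, a coding peak of Cat (catalase) with a log2 change of -1.67 ± 0.48 (fitted change ± SE, n = 3 each; edgeR quasi-likelihood adjusted p = 0.019). Adjusted over the list alone 0 of these passed, and the call was lost without KO Ago library 3 (camera adjusted p = 0.22 for the list). Of 2 peaks of cytochrome c oxidase assembly genes 0 passed by the edgeR quasi-likelihood test or DESeq2, with 1 higher at an unadjusted p under 0.05, by limma-voom and adjusted over the list alone (camera adjusted p = 0.56). The 3 macrophage, 2 progenitor and 12 granulocyte peaks and the 4 peaks of abundant noncoding RNA, all in Malat1, held 0 calls by the edgeR quasi-likelihood test, DESeq2 or limma-voom, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Their camera adjusted p were 0.57, 0.66, 0.65 and 0.57. Megakaryocyte genes had 0 tested peaks. Of the noncoding classes, Mir genes had 1 peak and mt- genes 41, and Snord and Snora genes 0, with 0 tested in each.

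By feature class, 160 of 903 tested 3′UTR peaks and 175 of 912 coding peaks were lower, with odds ratios against all other peaks of 1.01 (0.806 to 1.26) and 1.18 (0.949 to 1.47). Intergenic peaks were less often lower, with 26 of 251 (odds ratio 0.509, 0.321 to 0.779, Fisher exact p = 8.7e-04, Benjamini-Hochberg adjusted p = 0.0052 over 6 classes). Lower peaks made up 16 of 74 in 5′UTRs, 38 of 196 in introns and 7 of 37 in pseudogenes, with Fisher exact adjusted p from 0.71 to 0.96. Among peaks with a miR-144-3p 6-mer or longer, 29 of 66 in 3′UTRs and 22 of 39 in coding sequence were lower, and the shares did not differ beyond counting error (odds ratio 0.609, 0.252 to 1.45, Fisher exact p = 0.23).

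In the authors' deposited table, 6651 peaks were listed, of which 2372 were lower and 86 higher at a false discovery rate of 0.05. All 6651 peaks, and none besides, met a lowest peak height of at least 3, an IgG ratio under 0.2 and a density over background above 5. Of these peaks, 1114 were also tested here, and the log2 changes of the authors' deposited table and of this fit had a correlation of 0.992 across peaks, which are not independent replicates. Of the 327 peaks lower in the authors' deposited table among the shared ones, 267 were lower here, and 161 peaks lower here were not in that table. Of the 24 shared peaks higher here, 2 were higher in the authors' deposited table, whose median log2 change was -0.65. In the authors' deposited table, 300 of 306 peaks with a miR-451a 6-mer or longer and 306 of 462 with a miR-144-3p one were lower. In the same authors' deposited table, the 3′UTR peaks of Rab14, a vesicle-trafficking GTPase, had log2 changes of -3.20 and -3.39.

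The comparison of Ago with IgG asked which sites the Ago precipitate held above antibody background. In WT liver, peaks in coding sequence and 3′UTRs were higher in Ago. A coding peak of the histone gene Hist2h2bb rose from 579 ± 226 CPM in IgG to 7054 ± 123 in Ago (SD, n = 3 each), and one of Ank1 (ankyrin of the red cell membrane) from 423 ± 183 to 6552 ± 2893. The coding peak of Gpx1 (glutathione peroxidase) had 116 Ago reads and 0 IgG reads, which is at least 21.5-fold higher with 3 reads over the group as the floor. The peak of Cd47, the surface signal against phagocytosis, had 1 IgG read and a ratio of 54.1 (9.48 to 2157). Reads exceeded IgG 33.1-fold for Tcp11l2 (11.1 to 162), 19.7-fold for Sri (8.30 to 61.5), 16.1-fold for Hist1h1b (7.23 to 44.4) and 11.7-fold for Slc25a37 (6.56 to 22.9). Ratios of 30.1 for Fau and 30.8 for Gm9843 rest on shared reads and are uncertain.

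Of 894 peaks tested in WT, 321 were higher in Ago and 339 lower by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and the 10 named genes had edgeR quasi-likelihood adjusted p = 2.4e-04 to 2.5e-04. In KO, of 645 tested, 258 were higher and 150 lower. Coding and 3′UTR peaks made up 142 and 109 of the higher peaks in WT and 95 and 70 in KO. Intergenic and intron peaks made up 240 and 70 of the lower peaks in WT and 119 and 19 in KO. They also made up 15 and 24 of the higher peaks in WT and 39 and 23 in KO. Among 504 peaks tested in both genotypes, 133 were higher in both, where independent lists would give 53.4, and 111 were lower in both, where they would give 50.2. The compared lists share no library. The balance of directions depended on scaling, since higher peaks were 48.6% of calls in WT with TMM but 59.4% with RLE, and 63.2% in KO but 38.2% with library size alone. The number lower in WT was 129 by DESeq2 and that in KO 62. Leaving out any Ago library left 47 to 50 higher peaks in WT and 46 to 59 in KO, with fewer libraries and fewer peaks tested. Of 140 lower peaks in WT that were still tested, 29 to 39 were then lower, and of 97 in KO 7 to 14. The median log2 change of all tested peaks moved from -0.14 to -0.67 in WT and from -0.17 to -0.90 in KO with library size alone.

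By list, 42 of 48 erythroid peaks were higher in Ago in WT (median log2 change 2.73, camera p = 3.0e-11, and p = 0.062 with an estimated correlation) and 16 of 19 in KO. Hepatocyte peaks were higher in Ago for 22 of 63 in WT and 54 of 62 in KO. Of peaks with a miR-16-5p 7-mer or longer, 30 of 32 were higher in WT and 19 of 19 in KO. Of peaks with a miR-451a match, 7 of 8 were higher in WT and 1 of 1 in KO, and of those with a miR-144-3p match 15 of 17 in WT and 0 of 2 in KO. Whether these shares differ between genotypes was not tested at the level of the list.

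The comparison of KO with WT in IgG libraries measured the background in the same way. The peaks with the smallest p had modest differences. An intergenic peak at chromosome 3, 101993872 to 101993892, had 4360 ± 967 CPM in WT and 2341 ± 285 in KO (SD, n = 3 each). A 3′UTR peak of Dram2 had a log2 change of -0.72 ± 0.31, an intron peak of Col6a6 -0.53 ± 0.23, an intergenic peak at chromosome 3, 62214860 to 62214880, -0.93 ± 0.41, and a peak of Gm26561 0.57 ± 0.29 (fitted change ± SE, n = 3 each). Of 190 tested peaks, 0 were called in either direction by the edgeR quasi-likelihood test (adjusted p = 0.98 at the lowest), with 2 at an unadjusted p under 0.05. DESeq2 and limma-voom called 0, with 0 and 4 at an unadjusted p under 0.05. The tested peaks held 2708 to 5389 reads per library, so most sites of the Ago comparison were below what could be tested here.

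The interaction asked whether the genotype difference was larger in Ago than in IgG libraries. Of 1364 tested peaks, 0 were called by the edgeR quasi-likelihood test, DESeq2 or limma-voom, with 54, 36 and 88 at an unadjusted p under 0.05. The 3′UTR peak of Tnrc6b had a log2 difference of -4.02 ± 1.18 (Ago minus IgG, fitted difference ± SE, edgeR quasi-likelihood adjusted p = 0.84). Intergenic peaks had -2.44 ± 0.71 on chromosome 15 and -2.30 ± 0.60 on chromosome 16. The peak on chromosome 16 had 4, 4 and 6 reads in WT Ago and 4, 2 and 3 in KO Ago. Its IgG reads were 2, 3 and 1 in WT and 6, 7 and 8 in KO, so the difference lay largely in IgG. The other peaks among the 5 with the smallest p had a group at 0, so no fitted difference is given. The coding peak of Gpx1 had 0, 0 and 0 reads in WT IgG and 3, 1 and 2 in KO IgG, and an intergenic peak on chromosome 13 had 0, 0 and 0 reads in WT Ago and 4, 1 and 1 in KO Ago. Of the 428 lower peaks, 70 were in this fit, and 66 of them had a negative difference (median -1.92 against 0.16 in other peaks), which is largely built in because they were chosen in the same Ago libraries. The 428 peaks held 33765 WT and 5549 KO Ago reads, and 1616 WT and 884 KO IgG reads. The 428 peaks held a median of 4 IgG reads over 6 libraries, and 36 held none, so few IgG reads were at hand to compare each peak with the background.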

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

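The tests of single mismatches by seed position, within peaks without a miR-144-3p code, were chosen after the result was seen, and the other tests of this part were written before their values were seen. The comparisons of seed match groups above set peaks with a partial seed match to a microRNA of the deleted locus among the other peaks. Several of these classes, some of whose peaks also hold a code of another microRNA of the locus, were lower in KO far more often than peaks with no code. For miR-451a, 29.0% of 31 peaks with a mismatch at seed position 4 were lower, 43.3% of 120 at position 5, 35.4% of 96 at position 6, 71.2% of 52 at position 7 and 71.4% of 7 with an offset 6-mer. The share was 10.2% among peaks with no miR-451a code. For miR-144-3p, 43.3% of 67 peaks with a mismatch at position 4 and 31.97% of 147 at position 7 were lower, against 13.9% with no code. Two-sided Fisher exact tests, Benjamini-Hochberg adjusted over 48 tests, gave adjusted p = 0.011, 4.6e-18, 1.2e-09, 6.5e-23, 7.6e-04, 7.6e-08 and 6.2e-07 in this order. The other classes did not pass (adjusted p from 0.066 up by the same Fisher exact tests). For miR-451a they were 29.4% of 17 at position 2 and 16.7% of 18 at position 3. For miR-144-3p they were 22.2% of 63 at position 2, 11.8% of 85 at position 3, 6.67% of 60 at position 5, 13.3% of 195 at position 6 and 30% of 20 with an offset 6-mer. For miR-144-5p they ran from 10.9% of 55 at position 5 to 26.1% of 46 at position 3, against 17.8% with no code. Tested peaks held no mismatch codes for the microRNAs outside the locus, so these classes have no comparison from outside it. Positions are numbered as in the deposited codes.

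Single mismatches to miR-451a were found in 334 tested peaks, of which 140 were lower, such as the peaks of Tnrc6b, Wdhd1 and Alas2. If a miR-144-3p match in the same peak were the cause, mismatch peaks with no miR-144-3p code would be lower no more often than the 6.28% of peaks without any code of the locus. Of 208 such peaks, 41.3% were lower (odds ratio 10.5, 7.20 to 15.3, Fisher exact p = 4.9e-36), which argues against it. In genes without another deposited peak that has an offset or fuller miR-451a match, 43.3% of 247 peaks were lower (Fisher exact p = 2.9e-44). This argues against a fuller match elsewhere in the deposited peaks of the transcript, while sequence outside the peaks was not searched. The shares may reflect binding of miR-451a with a tolerated mismatch, most often at position 7 (29 of 41) and in 0 of 14 at position 3, and this stays a hypothesis found and tested on the same data.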

How the results depend on the processing

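The alternatives chosen after the data were seen were the authors' filtered peaks, identical peaks counted once, maximum coverage in place of reads, leaving out WT 10 and KO 13 together, and library-order pairs as a block. No paired analysis was possible because the groups share no replicate numbers in the labels, and the block is an alternative on pairs inferred from the data. The search over sites extended by 25 nt and the other seed families (let-7 and the rest) were not run, since no genome sequence was at hand, and a pseudocount alternative did not apply because the values are counts. Comparison-level values were rated the same where a count stayed within a fixed ratio of the main count, or where the call of a set was unchanged. Outside leave-one-out, 145 of these values were the same, 20 counts moved, and 3 set values became stronger, 3 weaker and 1 reversed. By leave-one-out, 125 were the same, 29 counts moved, and 10 set values became stronger, 7 weaker and 0 reversed. Of 626 values for 35 named peaks, 574 stayed on their side of the threshold, 52 lost the call and 0 called values changed sign. The number of peaks higher in KO was 69 with library size alone, 7 by DESeq2, 3 with all 12 libraries in 1 fit, 1 among peaks higher in Ago than in IgG, 297 among the authors' peaks, 14 without WT 10 and KO 13, 201 with the block, and 3 to 54 by leave-one-out. The number lower was 2704 with no filter, 58 with all 12 libraries, 62 among Ago-enriched peaks, 1898 among the authors' peaks, and 304 to 986 by leave-one-out. These fits tested 106381, 1364, 497, 6651 and 2148 to 4976 peaks in this order, against 2425 before, and the number called can change with the number tested. Peaks that were still tested also lost the call. Of the 428 lower peaks, 70 were tested with all 12 libraries and 44 stayed lower. Without WT 10 and KO 13 together, 311 of 428 stayed lower. Among Ago-enriched peaks 62 of 64 did, and among the authors' peaks 265 of 267. For Ago against IgG in WT, the number higher was 4303 with no filter and 47 to 1081 by leave-one-out, and the number lower 184 with the stricter filter, 129 by DESeq2 and 29 to 555. In KO the number higher was 1865 with no filter, 402 with the stricter filter and 46 to 697 by leave-one-out, and the number lower 315 with library size alone, 62 by DESeq2 and 8 to 464. In IgG libraries 1 peak was higher with no filter. Against other peaks, the miR-144-3p shift was -0.71 with 6-mers alone and -2.27 with 8-mers alone, beside -1.42 before. That of miR-451a was -3.82 with 6-mers alone and -1.85 with 8-mers alone (2 peaks, camera p = 0.13 with an estimated correlation), beside -3.10 before. The miR-144-5p shift was -2.20 with 8-mers alone (stronger, 3 peaks, camera p = 0.069 with an estimated correlation), that of miR-16-5p -0.078 with 6-mers alone (reversed), and that of miR-122-5p 0.42 with 8-mers and 0.0203 with 6-mers alone (both no longer called). Leave-one-out gave -0.39 to 0.051 for miR-144-5p, 0.039 to 0.25 for miR-16-5p, 0.037 to 0.34 for miR-21a-5p and 0.18 to 0.57 for miR-122-5p. Without WT 10 and KO 13, medians were -0.20 for literature targets (weaker), 0.51 for the Ago pathway and -1.65 for 14-3-3 (both stronger), judged like the other sets by the unadjusted camera p, and with an estimated correlation p was 0.17 and 0.18 for the last 2. Leave-one-out medians were -1.61 to -0.18 for literature targets, 0.26 to 0.62 for the Ago pathway, -1.74 to -0.34 for 14-3-3 and 0.017 to 0.42 for FoxO3. The authors' table held 34 higher peaks at the stricter threshold. For these changes the cause was not tested. The interaction recovered 17% of simulated 4-fold changes, while the IgG fit recovered 94.7% of 4-fold but 10.5% of 2-fold changes in its 190 peaks. Whether depth, the number of libraries or their spread set these limits was not tested.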

Other observations

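In this part, the splits counting called peaks, the comparison of hepatocyte peaks with other peaks and the count of genes without another peak were chosen after the result was seen, as were the genes of this paragraph. Among genes with at least 3 lower peaks in KO Ago libraries, 5 with roles in cell division or DNA topology are given as examples, and no such list was fixed or tested. All 3 tested peaks of Nek2 were lower, 3 of 5 of Prc1 (a spindle midzone protein), 3 of 5 of Top1, 3 of 11 of Top2a (topoisomerases) and 4 of 12 of Mki67 (the Ki-67 antigen). Of these, 2 lower peaks of Nek2 and 1 of Prc1 held a miR-451a 6-mer or longer, and 0 of Top1, Top2a and Mki67. Abcb10, a mitochondrial transporter of erythroid cells, held 4 lower peaks of 8, of which 0 held a miR-451a or miR-144-3p 6-mer or longer.

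Several literature targets had no peak past the filter. Summed over peaks and not scaled for depth, Cox10, a gene of haem A synthesis, had 34 WT and 6 KO Ago reads, Myc 146 and 103, Rab14 368 and 308, Mtor 93 and 110, Klf2 17 and 23, Zeb2 186 and 201, and Gata2 had no peak. The mean library total was 315681 reads in WT Ago and 229277 in KO Ago, and the sums were not tested. In the authors' deposited table, Zeb2, a transcriptional repressor, had 3′UTR peaks higher in KO with log2 changes of 3.36 and 2.21 and a coding peak with a miR-451a 6-mer at -3.38. 

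Among the 428 lower peaks, 76 in 66 genes and 3 intergenic sites had no code of the locus, such as the peak of Ybx1, with a median log2 change of -2.23. Other peaks without a code in 32 of these genes had a median of -0.11 (95% bootstrap interval -0.28 to 0.09, 117 peaks, 13 of them lower). This lay above the bound of -1.12, which argues against a fall in transcript abundance as large as that bound in these 32 genes. The interval also lay below 0.21, the median of all 1210 peaks without a code, so a smaller fall stays open. The test against the bound was narrowed to genes with another peak without a code after its value was seen. In 34 genes there was none, so abundance there cannot be told apart. Peaks with exactly the same counts elsewhere made up 5.26% (4 of 76, 1.45 to 12.9), which argues against reads shared with an exact copy for most. This count could not see copies with nearly the same counts, such as Fau and Gm9843, so shared reads of that kind stay open. A neighbouring peak with a seed code was found for 8 of 76 lower and 60 of 1134 other peaks (odds ratio 2.10, 0.835 to 4.66, Fisher exact p = 0.068), so a match just outside the searched interval may contribute and stays open.

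Hepatocyte peaks lay above other peaks without a code by 0.21 at the median (95% bootstrap interval over genes 0.12 to 0.29, bound 0.1). The gap depended on which library was left out, at -0.14 without WT Ago library 1, -0.09 without WT Ago library 9, -0.04 without KO Ago library 13 and 0.65 without WT Ago library 10. Each such fit also splits a number-ordered pair, and the gap was not computed with the pairs kept together. An equal rise of all other peaks from the loss of bound reads therefore cannot be told apart from a shift of hepatocyte genes. The lowest KO minus the highest WT share of hepatocyte reads was -0.877 percentage points in Ago libraries and -0.747 in IgG. Such overlap was set beforehand as evidence against more hepatocyte RNA in KO livers. That criterion was wrong because it ignored variation shared by libraries in number order, and within such pairs KO was higher in 3 of 3 Ago and 2 of 3 IgG pairs. This reading was chosen after the values were seen, so more hepatocyte RNA may explain the shift and cannot be excluded, and a biological difference between genotypes stays open as well.

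The splits of the 6 libraries number 10, the real one included, too few for a share under 0.05, and the real split alone gave the result in 1 of 10 for each of the following. The real and the highest other value were 462 and 0 called peaks for KO against WT in Ago, 660 and 0 for Ago against IgG in WT, 408 and 0 in KO, a median shift of 3.10 and 1.03 for miR-451a and 1.42 and 0.635 for miR-144-3p. In IgG libraries the genotype split called 0 peaks and the highest other 36. With 0 real calls, 10 of 10 splits give as many by construction, which says nothing about chance. The split with 36 calls set WT 2, WT 11 and KO 14 against WT 6, KO 4 and KO 8, and points to a structure of the samples beside genotype. For the interaction the real split called 0 peaks and the highest other 25. Here too 100 of 100 drawn splits give as many by construction, and no called peak is left for chance to explain.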
